A study of Manihot esculenta with 9 samples.

How the data were processed

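Leaf RNA of cassava (Manihot esculenta) was sequenced in 3 groups of 3 libraries each. The groups were wild type (WT) and a pair of transgenic lines, HOE1 and HOE8, that overexpress the linker histone gene MeH1.2. Per the labels' protocols, the plants were seedlings raised for 2 months from stem cuttings in closed sterile culture, without treatment, and the leaves were frozen before RNA extraction. The labels number the libraries of a group 1 to 3 but do not say that these came from separate plants or pools, and they give no collection time or batch. The p-values therefore measure only the spread between these libraries, which may be partly technical. The group of each library was taken from its genotype label.

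The deposited table of the whole series held, per gene and library, a whole-number read count and an FPKM value. HISAT2 version 2.0.4 and StringTie version 1.3.0 are named in the submitters' processing notes. The genome build, the counting settings, the sequencing kit and whether counting used strand are not given in the sources used here. The deposited FPKM values equalled the count divided by gene length and library total, so they carried no depth information beyond the counts. Each gene in the table had a Manes identifier, chromosome coordinates, a best Arabidopsis match and an Arabidopsis-style description. Gene functions given below are those of the Arabidopsis match and were not tested in cassava. None of the 33033 identifiers matched the separate gene table given for this species, which was not used. The file held no GO or KEGG terms, so no term enrichment was run. Overlapping genes and near-identical copies may have shared reads, and reads of the transgene cannot be told from those of the native gene with the same coding sequence.

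Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept with the edgeR filter at a minimum count of 10, which left 23434 and removed 9599. Libraries were scaled by TMM, and 1 quasi-likelihood model was fitted to all 9 libraries, so that the groups shared an estimate of the spread. The contrasts were HOE1 against WT, HOE8 against WT, the mean of both lines against WT, and HOE8 against HOE1. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors were obtained as the log2 fold change divided by the square root of the F statistic. Expression is given as TMM-scaled CPM, mean ± SD of 3 libraries. Where a group had 0 reads for a gene, the fold was computed against 3 reads over the group and is a lower bound. Where it had 1 to 3 reads, the ratio is given with its 95% exact counting interval, which covers counting error only. Fitted fold changes of such genes depend on the prior count.

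Library totals ran from 13272047 to 16378389 counted reads, so that 3 reads were worth 0.183 to 0.226 CPM in single libraries. On simulated counts for HOE1 against WT over 23073 genes, the test recovered 61.2% of 67 genes changed by 1.5-fold, 88.1% of 67 changed by 2-fold and 97% of 66 changed by 4-fold, with 8 false calls among 22873 unchanged genes. The changed genes were drawn from those above a minimum mean count. A far larger share of genes was called in the data, so recovery there may differ. The common biological coefficient of variation was 12.1%.

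Gene lists were word patterns on the descriptions. Of 42 lists fixed before the data were examined, 38 had at least 5 tested members. The lists for linker histones, cyanogenic glucosides, aquaporins and guard cells matched too few descriptions, with 1, 0, 2 and 3 tested members. A further 8 lists were written after the wording of the annotation had been read, and 2 more after values had been seen. Lists were tested with camera from limma, at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the fixed lists (for added lists, over all lists) in each contrast. The test with an estimated correlation also has fewer degrees of freedom, which by itself raises the p-values. On simulated data, the planted list and 1 other were called. The described lists were chosen from those tested after their results were known. Some patterns caught other genes: the fixed clock list held lipases whose description contains the letters of a clock gene, the list for wax and cutin held the seed albumin and lipid-transfer family, and the cell cycle list held cycling DOF factors, which are clock-linked regulators. The clock was therefore described with a list built on Arabidopsis matches.

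The named genes followed a rule fixed before the data were examined, except that fewer members of each described list were named than the rule allowed. It took the linker histone genes; the 8 higher and 8 lower genes with the largest fold change per contrast, and likewise for genes called the same way in both lines, among described genes with non-overlapping libraries and a mean of at least 1 CPM; and the leading members of each described list. Genes without a description were counted and not named under this rule. Overlapping genes, and the examples of neighbouring genes and of departing libraries, were named outside it, some without a description. For chance overlap between comparisons that share the WT libraries, unchanged groups were simulated in 20 draws.

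The alternatives tried were DESeq2 size factors and upper-quartile scaling, no filter and a filter of 10 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1), the compared groups alone, the replicate number as a block, a 2-fold minimum, and leaving out each library in turn. Another, leaving out genes in which 1 library departed from both others of its group, was added after the data were seen. The closing section gives their effect.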

Results

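The series measured leaf gene expression by RNA sequencing in wild-type cassava and in a pair of transgenic lines, HOE1 and HOE8, that overexpress MeH1.2, a linker histone. Linker histones bind the DNA between nucleosomes and help compact chromatin. Each group had 3 libraries. Total counts were 13923803, 14877089 and 16378389 in WT, 14373319, 15497815 and 15717369 in HOE1, and 13598923, 13272047 and 14015527 in HOE8. Between 26679 and 27226 genes had reads in a library. Libraries of a group differed by more than sampling noise in every pair, and HOE8 library 1 stood apart from libraries 2 and 3 of its group, with median chi-square values per gene of 1.98 and 2.21 against 0.782 between those libraries (0.455 for sampling noise alone). The first principal component held 65.6% of the variance and the second 23.4%.

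The linker histone genes were examined first, as a check of the labels. Among 6 genes whose best Arabidopsis match is a linker histone, Manes.08G136300 (chromosome 8, 30254598 to 30255861) carried the large increase in both lines. It measured 149 ± 7.9 CPM in WT, 4620 ± 110 CPM in HOE1 and 3350 ± 260 CPM in HOE8 (SD, n = 3). Its log2 fold change was 4.96 ± 0.07 (SE) in HOE1 (edgeR adjusted p = 2.5e-11) and 4.49 ± 0.07 in HOE8 (adjusted p = 1.8e-12), and HOE8 lay below HOE1 (log2 fold change -0.46 ± 0.06, adjusted p = 3e-05). The count holds native and transgene reads together, and the gene overlaps the end of its neighbour Manes.08G136400, an oxidoreductase gene, which had 1184, 1688 and 971 reads over the WT, HOE1 and HOE8 libraries. Manes.01G144600, annotated as histone H1-3 (chromosome 1, 25655688 to 25656952), rose from 554 ± 31 CPM to 1150 ± 35 in HOE1 and 1270 ± 140 in HOE8, with log2 fold changes of 1.05 and 1.20. Manes.08G136200, a neighbour of the main gene (chromosome 8, 30249619 to 30250714), rose from 60 ± 5.5 CPM to 82.9 ± 2.8 and 111 ± 9.5. Manes.15G036800 (chromosome 15, 2766081 to 2767196, overlapping Manes.15G036900) rose by 0.84 in HOE1 and 0.75 in HOE8 on the log2 scale. Manes.05G086000 (chromosome 5, 6685959 to 6687104) and Manes.01G224200 (chromosome 1, 30979076 to 30979974) rose in HOE8, by 0.76 and 3.85. In HOE1 their log2 fold changes were 0.07 (adjusted p = 0.41) and 0.54 (adjusted p = 0.16). As a list, written after the annotation had been read, 4 of the 6 were higher in HOE1 (set adjusted p = 0.018, and adjusted p = 0.52 with an estimated correlation) and 6 in HOE8 (set adjusted p = 0.0026, and adjusted p = 0.36 with an estimated correlation). The list holds Manes.08G136300 itself, so these set values do not show that the other linker histone genes rose as a set. The list was not tested without that gene.

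**Figure D1:**
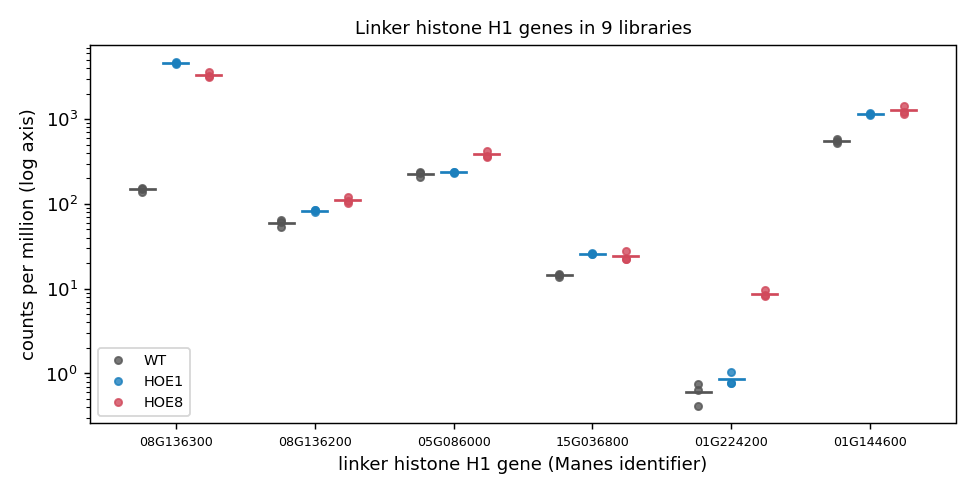
CPM (log axis) of the 6 genes with a linker histone as best Arabidopsis match, 1 point per library and a bar at the group mean (n = 3 per group). Manes.08G136300 stood at 149 CPM in WT, 4620 in HOE1 and 3350 in HOE8.

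The comparison of HOE1 with WT asked which transcripts differ in a line with the raised linker histone. In HOE1 leaves, transcripts of the photosynthetic apparatus, cell cycle proteins and chromatin modifiers were higher, and those of ribosomal proteins, of a list of wax, cutin and lipid-transfer genes, and of xylem and secondary-wall markers were lower. With an estimated correlation, 0 of the 7 list calls behind these groups passed the threshold. Large losses of single genes included cytochrome P450 genes. Manes.12G133500, best match CYP79B2, fell from 53.9 ± 2.6 CPM to 0.23 ± 0.23 (log2 fold change -7.86 ± 0.24, adjusted p = 9e-10). CYP79 enzymes turn amino acids into oximes, in cassava the entry step of cyanogenic glucoside synthesis. Of 23434 genes tested, 15082 (64.4%) passed the threshold, 7417 higher and 7665 lower. At 2-fold or more, 1993 were higher and 2530 lower. Non-overlapping libraries were found for 73.3% of genes, where chance gives 10%.

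Among the named losses in HOE1, 3 genes matching CYP83B1, an oxime-metabolising P450, fell together. Manes.05G139600 went from 63 ± 3.1 to 0.378 ± 0.066 CPM, Manes.05G139700 from 45.6 ± 6.4 to 0.445 ± 0.071, and Manes.05G150000 from 58.5 ± 3.9 to 0.58 ± 0.11. As close copies they may have shared reads. A second CYP79B2 match, Manes.13G094200, had 4.67 ± 0.48 CPM in WT, 211-fold above HOE1 (95% counting interval 37.4 to 8360). Manes.01G233100, matching a ubiquitin-like autophagy protein of the ATG8 family, had 27.7 ± 0.38 CPM in WT, 1240-fold above HOE1 (interval 223 to 49100). Manes.15G025200, a Rossmann-fold reductase, fell from 31.9 ± 0.35 to 0.399 ± 0.17 CPM. Manes.08G131300, a cupin, had 1.15 ± 0.24 CPM in WT and 0 reads in HOE1, at least 17.2-fold lower. Genes silent in WT appeared in HOE1: Manes.04G056700, an ARM repeat protein, was at least 48.3-fold higher, the rhomboid protease gene Manes.01G172600 at least 47.9-fold, Manes.18G123700, matching the gibberellin-linked CYP714A1, at least 29.4-fold, and Manes.16G054700, matching the sesquiterpene synthase TPS21, at least 12.9-fold. Manes.01G045700, matching the defence regulator WRKY18, was 92.3-fold higher (interval 16.1 to 3690), and the wound-responsive gene Manes.13G152300 was 42.3-fold higher (interval 14.1 to 208). Manes.10G149500, a beta glucosidase, rose from 1.62 ± 0.2 to 49.1 ± 0.45 CPM (log2 fold change 4.92 ± 0.08, adjusted p = 3.7e-11).

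Of 76 light-harvesting and photosystem genes, 57 were higher in HOE1, 3 lower and 16 not called (59 higher and 3 lower when adjusted over the list alone), and the list was higher as a set (camera adjusted p = 3.8e-10, and adjusted p = 0.51 with an estimated correlation). Manes.13G058600, a photosystem I antenna protein, rose from 99.6 ± 3.4 to 463 ± 13 CPM, and Manes.15G183900, a photosystem II antenna protein, from 65.8 ± 5.1 to 194 ± 4.2. Of 21 Calvin cycle genes, 15 were higher and 4 lower (15 and 4 adjusted over the list alone; set adjusted p = 0.0025, and adjusted p = 0.43 with an estimated correlation). Rubisco activase Manes.10G027600 rose from 606 ± 18 to 2050 ± 39 CPM and phosphoribulokinase Manes.15G185100 from 150 ± 3.6 to 388 ± 4.6. Clock genes moved with these groups: of 24 genes matched to the Arabidopsis clock, 16 were higher and 2 lower in HOE1 (adjusted p = 0.0016 for a list written after the annotation had been read, and adjusted p = 0.51 with an estimated correlation).

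Of 50 chromatin modifier genes, 30 were higher in HOE1 and 6 lower (30 and 7 adjusted over the list alone; set adjusted p = 0.0098, and adjusted p = 0.54 with an estimated correlation). Manes.01G202300, a histone acetyltransferase of the GNAT family, rose from 20.3 ± 0.13 to 42.1 ± 0.66 CPM, and Manes.09G037800, chromomethylase 1, a DNA methyltransferase of non-CG sites, from 1.63 ± 0.26 to 3.95 ± 0.74. Of 122 genes on the cell cycle list, 52 were higher and 21 lower (51 and 21 adjusted over the list alone; set adjusted p = 0.011, and adjusted p = 0.37 with an estimated correlation). Its leading members were not cell cycle genes: Manes.14G079000, a cycling DOF factor that overlaps Manes.14G079100, rose from 5.47 ± 0.17 to 16.9 ± 1.8 CPM, and Manes.12G126900, a kinesin-like protein of chloroplast movement, from 35.7 ± 1.1 to 89.7 ± 1.5. Without the cycling DOF factors, 48 of 115 were higher and 20 lower (adjusted p = 0.018, and adjusted p = 0.34 with an estimated correlation). Core histone genes were not called as a set in HOE1, with 2 of 18 higher and 4 lower (2 and 4 adjusted over the list alone; adjusted p = 0.8).

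All 12 cytosolic ribosomal protein genes called in HOE1, of 14 on the list, were lower (12 adjusted over the list alone; set adjusted p = 0.0013, and adjusted p = 0.55 with an estimated correlation). Manes.04G149400, 40S protein SA, fell from 35.4 ± 1.1 to 18.6 ± 0.47 CPM, and Manes.05G016600, a 60S acidic protein, from 30.8 ± 2 to 11 ± 0.83. The wider list of ribosomal proteins of all compartments, written after the annotation had been read, had 224 of 356 lower and 41 higher (adjusted p = 1.4e-06, and adjusted p = 0.82 with an estimated correlation). Of 76 genes on the wax and cutin list, 36 are of the lipid-transfer and 2S albumin family. In the list, 44 were lower and 12 higher (44 and 12 adjusted over the list alone; set adjusted p = 0.0013, and adjusted p = 0.51 with an estimated correlation). Split after the result was seen, the family had 18 of 36 lower and 5 higher, and the other members 26 of 40 lower and 7 higher. Manes.14G166500, lipid transfer protein 3, fell from 1060 ± 19 to 39 ± 1.2 CPM (log2 fold change -4.76 ± 0.08, adjusted p = 3.7e-11), and Manes.14G102100, 3-ketoacyl-CoA synthase 6, which makes wax precursors, from 213 ± 9.7 to 17.7 ± 0.91. Of 22 xylem and secondary-wall markers, 16 were lower and 2 higher (17 and 2 adjusted over the list alone; set adjusted p = 0.0098, and adjusted p = 0.37 with an estimated correlation). The members named were laccases, a family of which some members polymerise lignin. Manes.08G083300 fell from 216 ± 8.9 to 35.8 ± 1.5 CPM and Manes.02G187200 from 53.6 ± 2.8 to 5.74 ± 0.29. Markers of phloem, shoot meristem, root and senescing leaf were not called as sets in HOE1 (adjusted p = 0.37, 0.9, 0.8 and 0.37), nor were heat shock proteins and chaperones, with 72 of 221 higher and 64 lower (70 and 60 adjusted over the list alone; adjusted p = 0.81).

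**Figure D2:**
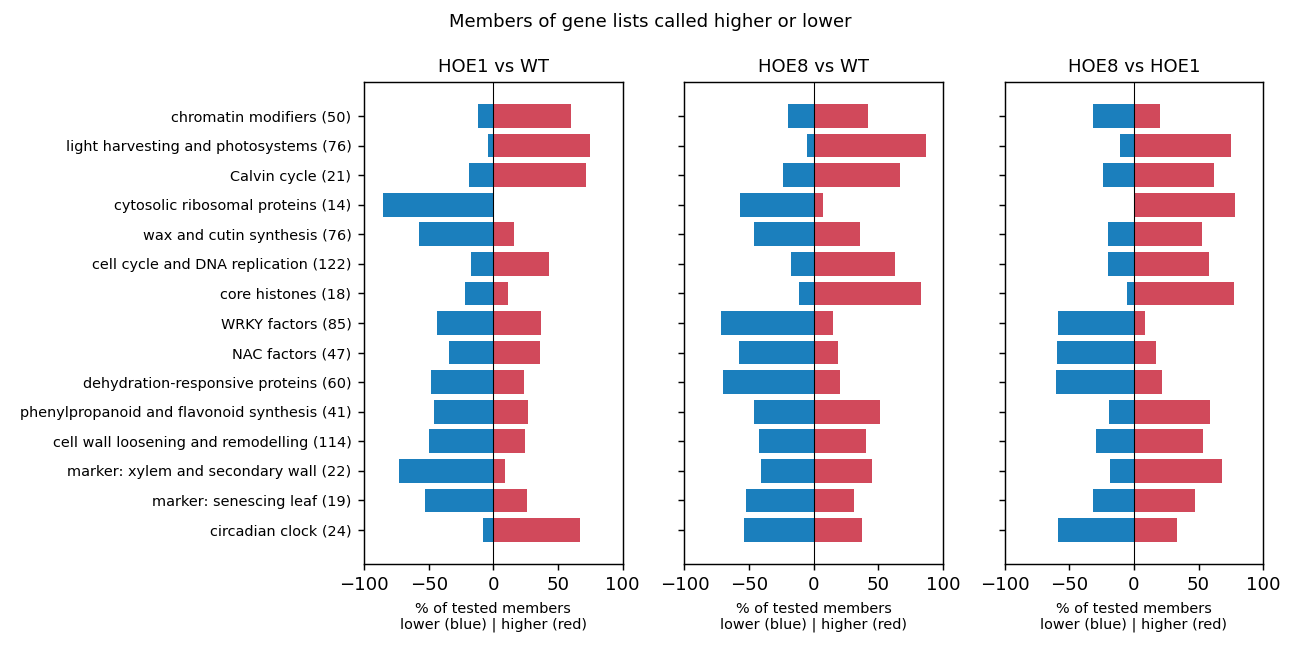
Percentage of tested members of 15 gene lists called higher (red, to the right) or lower (blue, to the left) in each comparison, with the number of members tested in brackets. Light-harvesting and photosystem genes had 57 of 76 members higher in HOE1 and 66 higher in HOE8, and WRKY factors had 61 of 85 lower in HOE8.

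HOE8 was set against WT in the same way. Transcripts of light harvesting, the Calvin cycle, the cell cycle and core histones were higher in HOE8 leaves, and those of WRKY and NAC factors and of dehydration-responsive proteins were lower. With an estimated correlation, 3 of these 7 list calls passed the threshold (cell cycle, WRKY and dehydration). Rubisco activase Manes.10G027600 rose from 606 ± 18 CPM in WT to 14800 ± 470 (log2 fold change 4.61 ± 0.04, adjusted p = 2.4e-13). The senescence-associated protease gene SAG12, Manes.16G038400, fell from 506 ± 8.1 to 0.277 ± 0.088 CPM (log2 fold change -10.79 ± 0.13, adjusted p = 1.2e-12). Of 23434 genes, 16841 (71.9%) passed the threshold, 7891 higher and 8950 lower. At 2-fold or more, 3587 were higher and 3894 lower, and 73.7% of genes had non-overlapping libraries, where chance gives 10%.

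Clock genes differed widely between HOE8 and WT. Manes.01G239000, matching the morning factor LHY, rose from 5.33 ± 0.5 to 1250 ± 160 CPM (log2 fold change 7.88 ± 0.12, adjusted p = 2.1e-12), and Manes.01G123100, matching RVE1, from 12.9 ± 1.2 to 465 ± 9.4. GIGANTEA, Manes.18G095000, an evening clock gene, fell from 480 ± 6.9 to 1.05 ± 0.3 CPM (log2 fold change -8.82 ± 0.12, adjusted p = 1.3e-12), and Manes.07G129600, matching the evening gene ELF4, was at least 144-fold lower. Of 24 clock matches, 9 were higher and 13 lower (set adjusted p = 0.67). Cycling DOF factor 3 genes, linked to the clock, rose as well: Manes.06G091600 went from 0.146 ± 0.068 to 71.4 ± 1.2 CPM. The labels give no time of collection, and the groups described next differed together with these genes.

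Of 76 light-harvesting and photosystem genes, 66 were higher in HOE8 and 4 lower (66 and 4 adjusted over the list alone; set adjusted p = 4.3e-16, and adjusted p = 0.34 with an estimated correlation). Manes.13G058600 reached 1830 ± 220 CPM and Manes.15G183900 reached 862 ± 24, while Manes.03G116700, a photosystem II antenna gene, rose from 13.1 ± 0.17 to 436 ± 36. Of 21 Calvin cycle genes, 14 were higher and 5 lower (14 and 5 adjusted over the list alone; set adjusted p = 0.0029, and adjusted p = 0.2 with an estimated correlation). Manes.14G018500, sigma factor E of the plastid RNA polymerase, rose from 0.902 ± 0.23 to 230 ± 3.8 CPM. Of the 122 cell cycle genes, 77 were higher and 21 lower (78 and 22 adjusted over the list alone; set adjusted p = 1.1e-05, and adjusted p = 0.041 with an estimated correlation). Without the cycling DOF factors, 71 of 115 were higher and 20 lower (adjusted p = 4.2e-05, and adjusted p = 0.038 with an estimated correlation). Of 18 core histone genes, 15 were higher and 2 lower (15 and 2 adjusted over the list alone; set adjusted p = 0.011, and adjusted p = 0.45 with an estimated correlation). Manes.05G083000, histone H2A 11, rose from 0.416 ± 0.2 to 7.12 ± 0.66 CPM, whereas Manes.03G018100, histone H2A 9, fell from 30.7 ± 1.9 to 2.87 ± 0.6. A wider list with genes described as histone superfamily, written after the annotation had been read, had 40 of 49 higher and 5 lower (adjusted p = 2.2e-05, and adjusted p = 0.5 with an estimated correlation). Its member Manes.14G013600 rose from 1.17 ± 0.068 to 17 ± 2.2 CPM. Of 50 chromatin modifiers, 21 were higher and 10 lower (21 and 10 adjusted over the list alone), and the set was not called (adjusted p = 0.17; without HOE8 library 1, adjusted p = 0.026). Manes.09G037800, chromomethylase 1, rose to 12.2 ± 1 CPM, and Manes.03G089100, chromomethylase 3, from 3.21 ± 0.14 to 17.4 ± 1.3.

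Of 85 WRKY factors, regulators of defence and senescence, 61 were lower in HOE8 and 13 higher (62 and 13 adjusted over the list alone; set adjusted p = 1.2e-05, and adjusted p = 0.041 with an estimated correlation). WRKY75, Manes.06G121200, fell from 76.3 ± 4.7 to 6.86 ± 0.81 CPM, WRKY40, Manes.04G102600, from 28 ± 1.8 to 2.82 ± 0.28, and WRKY33, Manes.09G112700, from 64.2 ± 2.7 to 12.9 ± 0.81. Of 47 NAC factors, 27 were lower and 9 higher (27 and 9 adjusted over the list alone; set adjusted p = 0.022, and adjusted p = 0.2 with an estimated correlation). That call ended when no count filter was applied (adjusted p = 0.079). NAC047 match Manes.09G144100 fell from 63.3 ± 3.8 to 6.1 ± 0.63 CPM. A second NAC047 match, Manes.08G147800, fell to 33.1 ± 2 CPM (log2 fold change -2.62 ± 0.06), and the NAC100 match Manes.06G090500 from 86.6 ± 3.2 to 26.5 ± 0.88. Of 60 dehydration-responsive genes, 42 were lower and 12 higher (42 and 12 adjusted over the list alone; set adjusted p = 0.00017, and adjusted p = 0.041 with an estimated correlation). Osmotin 34, Manes.02G025200, fell from 692 ± 31 to 5.99 ± 1.4 CPM and the LEA gene Manes.11G052600 from 92.2 ± 5.3 to 3.37 ± 0.17. The list also held cold regulated gene 27, Manes.18G037600, whose description does not name dehydration. It fell from 53.8 ± 2.1 to 1 ± 0.42 CPM in HOE8 but rose to 113 ± 0.42 in HOE1. Cytosolic ribosomal proteins and the lists for wax and cutin, phenylpropanoids and cell wall remodelling were not called in HOE8 against WT (adjusted p = 0.66, 0.76, 0.76 and 0.76). The 19 senescing-leaf markers were not called as a set, with 10 lower and 6 higher (10 and 6 adjusted over the list alone; adjusted p = 0.57). Xylem, phloem, shoot meristem and root markers (adjusted p = 0.92, 0.76, 0.29 and 0.94) and heat shock proteins (adjusted p = 0.71) were not called either. Of 16 shoot meristem markers, 10 were higher and 4 lower (10 and 4 adjusted over the list alone), with a median log2 fold change of 1.16.

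Other large changes in HOE8 were found in single genes. Seed storage albumin 2, Manes.15G075900, the oil body protein oleosin 1, Manes.06G131000, and the seed-type LEA gene Manes.10G010700 had 10.6 ± 1.6, 12.8 ± 0.94 and 11.9 ± 1.4 CPM in WT and 0 reads in HOE8, at least 140-fold, 170-fold and 157-fold lower. Manes.04G115700, a glyoxalase I family gene, had 19.1 ± 1.4 CPM in WT and 0 reads in HOE8, at least 253-fold lower. Manes.07G020700 and Manes.10G124800 encode B3-type factors. The first fell from 175 ± 2.2 to 0.128 ± 0.16 CPM, and the second was at least 219-fold lower, from 16.5 ± 1.8 CPM. Manes.03G201700, matching MYB111, a regulator of flavonol synthesis, had 0 reads in WT and 5.54 ± 0.043 CPM in HOE8, at least 86.8-fold higher. TPS21 matches Manes.16G054700 and Manes.16G057600 were at least 283-fold and 47.4-fold higher, the NPH3 family gene Manes.12G134700 was 1550-fold higher (interval 279 to 61500), and Manes.08G135800, an acyltransferase, rose from 0.131 ± 0.14 to 58.1 ± 4.2 CPM. CYP714A1 match Manes.18G123400 was 567-fold higher (interval 157 to 4690).

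**Figure D3:**
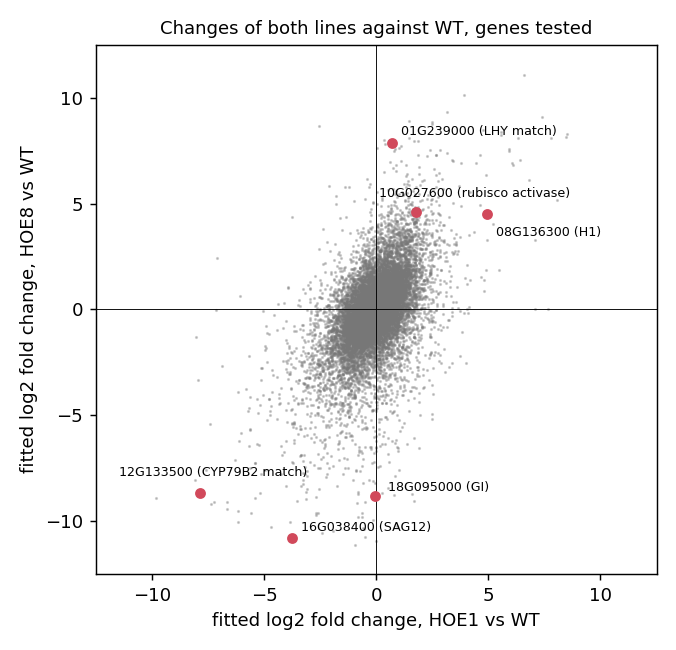
Fitted log2 fold change against WT in HOE1 (x axis) and HOE8 (y axis), 1 point per gene tested (23434), with 6 named genes in red. Manes.08G136300 rose in both lines (4.96 and 4.49), while GIGANTEA, Manes.18G095000, lay at -0.04 in HOE1 and -8.82 in HOE8.

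The genes called in both lines addressed what the lines have in common. The same way in both lines were 9585 genes, 4430 higher and 5155 lower, where independent lists of these sizes give 2498 and 2927. At 2-fold or more there were 1119 higher and 1470 lower. In 20 simulated draws with no effect and shared WT libraries, at most 1 gene was called the same way in both. The draws held only the spread between libraries of a group. They cannot exclude a shift of the whole WT group, which would enter both comparisons. The fold changes of the lines had the same sign in 70.1% of genes (66.5% simulated), a Pearson correlation across genes of 0.539 (0.501 simulated) and a covariance of 0.807 (0.022 simulated). The simulated share and correlation are set by the shared WT libraries, whatever the size of the spread. They are therefore no baseline for data in which most genes were called. Only the covariance compares sizes. Genes are not independent replicates. The 3 WT libraries were not split, since 1 part would hold a single library, and part of the excess over independent lists may come from the shared controls. Opposite calls were made for 2231 genes. The mean of both lines differed from WT in 16439 genes, 7689 higher and 8750 lower. This count also takes in genes that changed in 1 line only, so it does not measure shared change. GIGANTEA, Manes.18G095000, was called with a mean log2 fold change of -4.43, although it lay at -0.04 in HOE1.

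Genes lost in both lines included P450 genes: Manes.12G133500 measured 0.23 ± 0.23 CPM in HOE1 and 0.125 ± 0.041 in HOE8 against 53.9 in WT, and its second match Manes.13G094200 was at least 62.2-fold lower in HOE8. CYP83B1 match Manes.05G139600 fell to 0.101 ± 0.17 CPM in HOE8, Manes.05G139700 was 607-fold lower (interval 207 to 2950) and Manes.05G150000 was 777-fold lower (interval 266 to 3770). Manes.01G233100 was 551-fold lower in HOE8 (interval 152 to 4550), Manes.15G025200 fell to 0.225 ± 0.069 CPM, and Manes.01G202400, a glutamine amidotransferase-like gene, fell from 115 ± 7.7 CPM to 1.58 ± 0.4 in HOE1 and 0.1 ± 0.12 in HOE8. Dihydroflavonol reductase, Manes.18G022300, an anthocyanin enzyme, fell from 88.9 ± 4.4 to 3.32 ± 0.28 and 2.77 ± 0.43 CPM, and SAG29, Manes.13G006800, from 99.3 ± 2.2 to 1.36 ± 0.17 and 6.74 ± 1.4. Neutral invertase Manes.08G109700, which splits sucrose, rose from 3.16 ± 0.61 to 78.7 ± 2.9 and 95.7 ± 0.46 CPM. Beta glucosidase Manes.10G149500 reached 131 ± 2.2 CPM in HOE8. Manes.04G056700, Manes.01G172600 and Manes.18G123700, silent in WT, were at least 41.8-fold, 37.5-fold and 36.7-fold higher in HOE8. WRKY18 match Manes.01G045700 was 166-fold higher (interval 29.3 to 6590) and Manes.13G152300 was 18.2-fold higher (interval 5.84 to 91.3) in HOE8. TPS21 match Manes.16G057600 was at least 3.5-fold higher in HOE1 (fitted log2 fold change 4.76, adjusted p = 0.026). Its call in HOE1 ended without WT library 2 (4.75), WT library 3 (4.74) or HOE1 library 1 (3.64), and with limma on log2(FPKM + 1) (0.16).

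The direct test of HOE8 against HOE1 showed that the lines differed in most genes. Relative to HOE1, HOE8 leaves had more transcript of photosynthesis, core histone, cell cycle and ribosomal protein genes and less of WRKY, NAC and dehydration-responsive genes. With an estimated correlation, 0 of 11 list calls between the lines passed the threshold. Of 23434 genes, 15577 (66.5%) passed the threshold, 7661 higher and 7916 lower in HOE8, with 3036 and 2986 at 2-fold or more. Of the 9585 genes called the same way in both lines, 5827 also differed between them, and 6128 (63.9%) had the larger absolute change in HOE8. GIGANTEA, Manes.18G095000, differed between the lines by a log2 fold change of -8.78 ± 0.12 (adjusted p = 2.1e-12), and the LHY match Manes.01G239000 by 7.18 ± 0.12 (adjusted p = 4.3e-12).

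Several named genes were near 0 in WT and HOE1 and abundant in HOE8. Manes.07G119800, an RCC1 family gene, measured 0.342 ± 0.15, 0.442 ± 0.24 and 78.5 ± 3.8 CPM in WT, HOE1 and HOE8. Manes.11G003200, a BAHD-type acyltransferase, measured 0.0882 ± 0.11, 0.0882 ± 0.098 and 18.5 ± 2.1. Manes.06G026900, a CAP family gene, measured 1 ± 0.14, 0.221 ± 0.096 and 58.1 ± 6.8, and Manes.03G209900, a pectin lyase-like gene, 0.426 ± 0.15, 0.154 ± 0.098 and 23.4 ± 1. Others were present in WT and HOE1 and had 0 reads in HOE8. The DnaJ-domain gene Manes.17G076700 (10.1 ± 0.7 and 19.2 ± 0.94 CPM) was at least 255-fold lower than in HOE1. Manes.13G043500, matching the seed maturation regulator ABI3 (4.44 ± 0.55 and 14.2 ± 0.43), was at least 189-fold lower, the carboxyesterase gene Manes.14G080200 (3.61 ± 0.64 and 10.9 ± 0.83) at least 144-fold, and Manes.18G071300, matching ALD1 of pipecolic acid synthesis (3.73 ± 0.49 and 6.48 ± 0.24), at least 85.9-fold.

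Between the lines, 57 of 76 light-harvesting genes were higher in HOE8 and 8 lower (57 and 8 adjusted over the list alone; set adjusted p = 6e-09, and adjusted p = 0.41 with an estimated correlation). Of 21 Calvin cycle genes 13 were higher and 5 lower (13 and 5 adjusted over the list alone; set adjusted p = 0.029, and adjusted p = 0.32 with an estimated correlation), a call that ended without HOE8 library 2 (adjusted p = 0.051). Core histones were higher in 14 of 18 and lower in 1 (15 and 1 adjusted over the list alone; set adjusted p = 0.0021, and adjusted p = 0.32 with an estimated correlation), and cytosolic ribosomal proteins in 11 of 14 and lower in 0 (12 and 0 adjusted over the list alone; set adjusted p = 0.0028, and adjusted p = 0.53 with an estimated correlation). The cell cycle list had 71 of 122 higher and 24 lower (72 and 24 adjusted over the list alone; set adjusted p = 0.00077, and adjusted p = 0.082 with an estimated correlation). Phenylpropanoid and flavonoid genes had 24 of 41 higher and 8 lower (24 and 9 adjusted over the list alone; set adjusted p = 0.014, and adjusted p = 0.26 with an estimated correlation). Hydroxycinnamoyl transferase Manes.06G034900, of lignin precursor synthesis, went from 27.8 ± 1.9 to 541 ± 31 CPM, while its relative Manes.11G067800 went from 80.9 ± 1.2 to 39 ± 0.72. The wax and cutin list had 40 of 76 higher and 15 lower (40 and 15 adjusted over the list alone; set adjusted p = 0.011, and adjusted p = 0.41 with an estimated correlation), 23 and 4 of them among the 36 of the lipid-transfer and 2S albumin family and 17 and 11 among the other 40. The lipid-transfer gene Manes.06G046800 went from 55.3 ± 1.4 to 707 ± 11 CPM. Cell wall remodelling genes had 61 of 114 higher and 33 lower (62 and 34 adjusted over the list alone; set adjusted p = 0.031, and adjusted p = 0.32 with an estimated correlation). That call ended without HOE8 library 1 or 2 (adjusted p = 0.051 each) and with no count filter (0.064). Xyloglucan endotransglycosylase 6, Manes.11G115200, went from 30.2 ± 1.3 to 251 ± 4 CPM, and expansin-like B1, Manes.17G018100, and Manes.17G015100, a xyloglucan hydrolase, from 13.3 ± 0.5 to 1.74 ± 0.14 and from 50.2 ± 2.1 to 9.36 ± 0.41.

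Lower in HOE8 than in HOE1 were 50 of 85 WRKY factors, with 7 higher (50 and 7 adjusted over the list alone; set adjusted p = 1.1e-05, and adjusted p = 0.082 with an estimated correlation). NAC factors had 28 of 47 lower and 8 higher (30 and 9 adjusted over the list alone; set adjusted p = 0.0019, and adjusted p = 0.11 with an estimated correlation), and dehydration-responsive genes 36 of 60 lower and 13 higher (37 and 13 adjusted over the list alone; set adjusted p = 0.0011, and adjusted p = 0.082 with an estimated correlation). In HOE1 itself these lists were not called against WT (adjusted p = 0.89, 0.97 and 0.15). Clock matches moved with these groups, 14 of 24 lower and 8 higher in HOE8 (set adjusted p = 0.17). The fixed clock list, of which part were lipases, was not called against WT in HOE1 (21 of 55 higher, 15 lower, adjusted p = 0.8) or HOE8 (27 and 21, adjusted p = 0.66), nor between the lines (29 and 19, adjusted p = 0.28). Chromatin modifiers and the xylem, senescing-leaf and phloem markers were not called between the lines (adjusted p = 0.64, 0.07, 0.64 and 0.08). Shoot meristem markers were not called either (adjusted p = 0.33), with 9 of 16 higher in HOE8 and 5 lower (median log2 fold change 1.07). The xylem markers, 15 of 22 higher in HOE8 and 4 lower, passed the threshold without HOE1 library 2 (adjusted p = 0.039) and with no count filter (0.041). The phloem markers, 8 of 15 lower and 3 higher (median log2 fold change -0.58), passed it without HOE8 library 1 and with no count filter (adjusted p = 0.04 each). Among the xylem markers, the named laccases Manes.08G083300 and Manes.02G187200 went against most of the list. Their log2 fold changes were -4.22 and -3.64 between the lines, and -6.81 and -6.86 in HOE8 against WT.

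**Figure D4:**
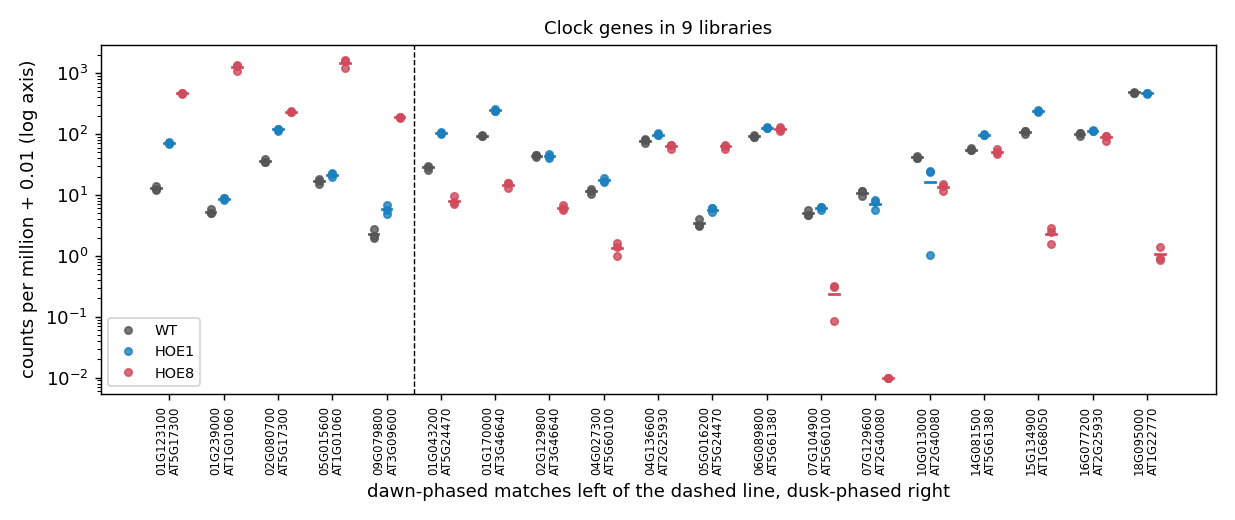
CPM plus 0.01 (log axis) of 19 genes matched to dawn-phased (left of the dashed line) or dusk-phased (right) Arabidopsis clock genes, 1 point per library and a bar at the group mean (n = 3 per group). All 5 dawn matches were higher in HOE8 than in WT, and 10 of 14 dusk matches were lower.

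**Figure D5:**
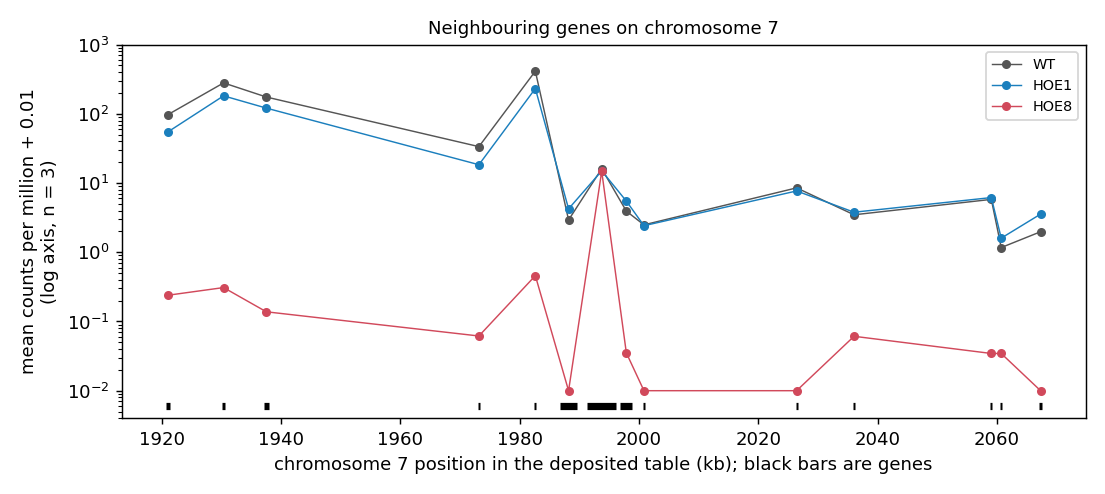
Mean CPM plus 0.01 (log axis, n = 3 libraries per group) of 14 tested neighbouring genes on chromosome 7, drawn at their position in kilobases, with genes as black bars. In HOE8, 12 of the 14 were at least 50-fold below both other groups, while Manes.07G021300 stayed at 14.8 CPM against 16.1 in WT.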

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

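The test between the lines was fixed before the data were examined, while the regroupings of libraries and the tests on clock genes and on neighbouring genes were chosen only after the result was seen. What singled out the results below is a difference between the transgenic lines by the HOE8 against HOE1 test, which 15577 genes passed. Of 85 named genes, 74 differed, but part of them had been chosen by this same test, so that share was partly fixed in advance. Over all genes tested the share was 66.5%.

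Values are log2 fold changes of HOE8 over HOE1 unless a fold is stated. Among linker histone genes they were -0.46 for Manes.08G136300, 3.32 for Manes.01G224200, 0.42 for Manes.08G136200 and 0.70 for Manes.05G086000. Among genes higher in both lines they were 4.44 and 3.71 for the TPS21 matches Manes.16G054700 and Manes.16G057600, 0.84 for Manes.01G045700, -1.21 for Manes.13G152300, 1.41 for Manes.10G149500 and 0.28 for Manes.08G109700. Among genes lower in both lines, Manes.01G202400 gave -3.86, Manes.13G006800 gave 2.30, and the CYP83B1 match Manes.05G139600 gave -1.83. Its copies Manes.05G139700 and Manes.05G150000 were 5.91-fold (counting interval 1.75 to 31) and 7.68-fold (2.35 to 39.6) higher in HOE1. The -1.83 of Manes.05G139600 lost its call without WT library 1, 2 or 3 (-1.83 each), HOE1 library 1 (-1.87), 2 (-1.93) or 3 (-1.68), or HOE8 library 2 (-1.3) or 3 (-1.26), with the stricter filter (-1.79) and with limma on log2(FPKM + 1) (-0.23).

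Genes far higher in HOE8 were Manes.12G134700 (6.18), Manes.18G123400 (7.40), Manes.06G091600 (6.35), Manes.08G135800 (6.24), Manes.06G026900 (7.97), Manes.14G018500 (7.62), Manes.11G003200 (7.57), Manes.07G119800 (7.43) and Manes.03G209900 (7.16). Manes.03G201700 was 82.8-fold higher (counting interval 28 to 405) and Manes.08G131300 at least 94.5-fold higher. Far lower were Manes.16G038400 (-7.07) and Manes.07G020700 (-9.81). With 0 reads in HOE8, the folds were at least 131 for Manes.04G115700, 218 for Manes.10G124800, 31.9 for Manes.06G131000, 41.6 for Manes.10G010700, 96 for Manes.07G129600, 5.31 for Manes.15G075900, 255 for Manes.17G076700, 189 for Manes.13G043500, 144 for Manes.14G080200 and 85.9 for Manes.18G071300.

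Among list members, photosynthesis genes gave 2.15 (Manes.15G183900), 1.98 (Manes.13G058600), 5.18 (Manes.03G116700), 2.85 (Manes.10G027600) and 0.69 (Manes.15G185100). Chromatin and histone genes gave 1.63 (Manes.09G037800), 2.12 (Manes.03G089100), -3.07 (Manes.03G018100), 2.72 (Manes.05G083000) and 3.03 (Manes.14G013600). On the cell cycle list, Manes.14G079000 gave 2.84 and Manes.12G126900 gave 1.91. Ribosomal genes gave 0.42 (Manes.04G149400) and 1.18 (Manes.05G016600), and lipid genes 0.54 (Manes.14G166500), 1.3 (Manes.14G102100) and 3.68 (Manes.06G046800). WRKY genes gave -2.14 (Manes.06G121200), -1.23 (Manes.04G102600) and -3.21 (Manes.09G112700). NAC genes gave -2.79 (Manes.09G144100), -0.93 (Manes.06G090500) and -3.16 (Manes.08G147800). Members of the dehydration list gave -2.59 (Manes.11G052600), -2.64 (Manes.02G025200) and -6.80 (Manes.18G037600, described as cold regulated). Phenylpropanoid genes gave -1.05 (Manes.11G067800) and 4.28 (Manes.06G034900), cell wall genes -2.42 (Manes.17G015100), -2.93 (Manes.17G018100) and 3.06 (Manes.11G115200), and laccases -4.22 (Manes.08G083300) and -3.64 (Manes.02G187200).

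Lists called between the lines had median log2 fold changes of 0.92 for core histones, 0.91 for photosystems, 0.27 for the Calvin cycle, 0.40 for cytosolic ribosomal proteins, 0.67 for phenylpropanoids, 0.51 for cell wall remodelling, 0.85 for the cell cycle, 0.48 for wax and cutin, -0.79 for dehydration, -0.84 for WRKY and -0.77 for NAC. With an estimated correlation, 0 of these 11 calls were kept.

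Regroupings of the libraries were counted for each comparison. For single comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05: HOE1 against WT gave 15082 genes and at most 3 in another split, HOE8 against WT 16841 and 1, and HOE8 against HOE1 15577 and 2. For regroupings of all 9 libraries into 3 groups, drawn at random besides the real one, 1 of 40, the real one, gave as many genes. This held for the mean of both lines (16439, highest other 10129) and for genes called the same way in both (9585, highest other 7396). Chance labelling of single libraries is argued against for these counts. Chance differences between plants, pools or batches cannot be excluded, because the libraries of a group may not come from separate plants. The highest other split kept 1 group whole.

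The first pattern weighed is the clock. LHY match Manes.01G239000 differed between the lines by 7.18, RVE1 match Manes.01G123100 by 2.71 and GIGANTEA, Manes.18G095000, by -8.78. In HOE8 against WT, 15 of 19 dawn or dusk genes moved as a collection time nearer dawn would move them, with medians of 6.37 for dawn and -2.23 for dusk genes. In HOE1, all 5 dawn genes were also higher (median 1.36), and of 14 dusk genes 8 were higher and 1 lower. If the effect rose with the linker histone transcript, which is higher in HOE1, the HOE1 dusk median would not exceed that of HOE8. It was 0.40, but a different collection time of HOE8 would also move dusk genes, so this cannot decide. Scaling between libraries is argued against by the gap of 8.61 between the dawn and dusk medians in HOE8. A factor per library leaves this gap as it is (8.45 or more in each HOE8 library, at most 0.11 between WT libraries). A collection at another time of day may account for the 15 genes and cannot be told apart from an effect of the line, because the labels give no time and all HOE8 libraries belong to 1 group.

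The second pattern is a set of neighbouring genes silent in HOE8. Counting genes at least 50-fold below both other groups gave 64 in HOE8, 5 in WT and 2 in HOE1. Of those in HOE8, 17 lay in 2 groups of neighbours. Several are tandem copies with the same Arabidopsis match, and 6 name a B3 domain or factor, so that they are not independent and no p-value is given for their clustering. On chromosome 7 (1920630 to 2067513, 147 kb) 12 of 14 genes were silent, at 1.26 CPM in HOE8 against 1030 in WT and 641 in HOE1, and on chromosome 10 (23606139 to 23669296, 63.2 kb) 5 of 5, at 0.127 against 28.4 and 27.4.

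For these neighbours, counts lost in single libraries, in any group alike, are argued against by 1 such value, 0.98% of those in the WT and HOE1 libraries, while all 17 genes were low over the HOE8 group. A loss of counts in all HOE8 libraries together was not tested. Such single losses did occur nearby: the ferredoxin-like gene Manes.07G020100 (1887447 to 1888439) had 48, 16300 and 16986 counts in HOE8 and 23, 6517 and 6541 in HOE1. One deletion spanning the neighbours on chromosome 7 is argued against by 1 gene inside the span, Manes.07G021300, at 14.8 CPM in HOE8 against 15 in HOE1. That holds only if its reads came from this place. Reads from a copy elsewhere and the gene order in these plants were not checked. One deletion spanning the neighbours on chromosome 10 could account for the 5 silent genes there, since 0 genes inside that span kept their level. Reads moved to paralogs stay open: other genes with the same Arabidopsis match gained 0.57% of the CPM lost, but such genes existed for only 3.16% of it. Silencing of the chromosome 7 genes in this line was not tested.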

How the results depend on the processing

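Leaving out genes in which 1 library departed from both others was chosen only after the data were seen; the other alternatives were fixed before. With a 2-fold minimum, the counts fell to 4523 (HOE1 against WT), 7481 (HOE8 against WT), 5361 (mean of both), 6022 (HOE8 against HOE1) and 2589 (the same way in both), since this adds a condition to the same calls. With an estimated correlation, 0, 3 and 0 of the fixed lists were called in HOE1, in HOE8 and between the lines, 3 of 25 in all. Some lists lost their call although their estimate lay below the preset 0.01. These were xylem markers (-0.029) and the cell cycle (0.0093) in HOE1, and dehydration (0.0035) and the cell cycle (0.0093) between the lines. Other lost lists had higher estimates, up to 0.62. A correlation above the preset therefore cannot be the cause for all of them. With an estimated correlation, camera also takes the residual degrees of freedom of the 9 libraries, far fewer than with a preset. Fewer degrees of freedom by themselves raise the p-values. How much each contributed was not tested.

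Under the other alternatives, leaving out libraries aside, each count stayed within 1.5 times its value. HOE1 against WT ran from 11367 (stricter filter) to 16111 (compared groups alone), HOE8 against WT from 11968 to 17574 (no filter), and HOE8 against HOE1 from 11175 to 16054. Without single libraries, the counts ran from 13927 to 16264, 16101 to 17294, 15252 to 17305 (mean of both), 14498 to 15785 and 8831 to 10412 (the same way in both), and lists called from 24 to 28. With the replicate number as a block they were 14843, 16624, 16226, 15298 and 9391, and the calls of Manes.16G057600 in HOE1 (4.77) and Manes.05G139600 between the lines (-1.83) ended. Without departing genes they were 15045, 16778, 16392, 15528 and 9567. DESeq2 called 14360, 16545 and 14953 genes in the line comparisons, of which 14000, 15838 and 14450 were also edgeR calls. The mean of both lines has no version with compared groups alone, and the pseudocount alternative did not apply to counts. Which direction held more calls depended on the scaling. HOE8 against HOE1 had 8606 higher and 7068 lower with upper-quartile scaling, and 7661 and 7916 with TMM. HOE1 against WT had 7600 higher and 7506 lower with DESeq2 size factors, and 7417 and 7665 with TMM. HOE8 against WT kept more lower calls, with 8378 higher and 8447 lower under upper-quartile scaling.

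Manes.08G136300 kept a mean log2 fold change of 4.68 to 4.75 without single libraries (4.72 with all). For named genes, 4495 of 4531 values kept direction and side of the threshold, 30 lost the call, 6 gained it and 0 reversed. In HOE1, Manes.03G209900 lost its call without WT library 1 (-1.20) or 3 (-1.31) or HOE1 library 1 (-1.09) or 3 (-1.28), with DESeq2 (-1.43) and with limma (-0.18), Manes.12G134700 with limma (0.18), and Manes.03G018100 without WT library 2 or HOE1 library 3 (-0.30 each). In HOE8, Manes.05G016600 lost its call without WT library 2 (-0.26) or 3 (-0.32) or HOE8 library 3 (-0.18), with upper-quartile scaling (-0.26) and with the compared groups alone (-0.27). The cause was not tested. In the simulated counts, where few genes were changed, 61.2% of 1.5-fold changes were recovered.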

Other observations

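The tests on enrichment of gene families and on single libraries that depart from their group were chosen only after the result was seen. Families sharing a description were compared between genes changed at least 2-fold and all genes tested, over 295 families, as exploration (one-sided Fisher's exact test, adjusted over families for each comparison and direction). Genes without a description were left out of both sides. Examples of those past the threshold follow. In HOE1, 11 of 13 CYP83B1 matches were lower (1.41 expected, adjusted p = 4.5e-07), as were 17 of 36 peroxidases (3.91, adjusted p = 6.3e-06), 18 of 54 S-locus lectin kinases, which are receptor-like (5.86, adjusted p = 0.00039), and 15 of 40 MATE transporters (4.34, adjusted p = 0.00039). Higher in HOE1 were 10 of 23 MLP-like proteins (1.92, adjusted p = 0.002) and 28 of 154 NB-ARC resistance proteins (12.9, adjusted p = 0.0053). The wider list of immune receptors, fixed before the data were examined, was not called in HOE1 (100 of 292 higher, 48 lower, camera adjusted p = 0.16) or HOE8 (95 higher, 71 lower, adjusted p = 0.53).

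In HOE8, 31 of 54 S-locus lectin kinases were lower (9.04 expected, adjusted p = 2.5e-09), with 11 of 13 CYP83B1 matches (2.18, adjusted p = 1.6e-05) and 17 of 31 cysteine-rich receptor-like kinases (5.19, adjusted p = 0.00011). Higher in HOE8 were 18 of 33 NPH3 proteins of light signalling (4.9, adjusted p = 3.8e-05), 10 of 17 B-box factors (2.52, adjusted p = 0.0012) and 43 of 154 NB-ARC proteins (22.9, adjusted p = 0.00099). Members of a family are often close copies that share reads, so they are not independent.

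In some genes, 1 library fell more than 5-fold below both others of its group, with those at 7 CPM or more. There were 296 such values in 237 genes, 19 to 41 per library, against 60 on the high side. Manes.15G039800 had 144, 105733 and 118108 counts in the WT libraries, Manes.07G020100 had 48, 16300 and 16986 in HOE8, and Manes.05G003500 had 9152, 23 and 10197 in WT and 190, 9417 and 17 in HOE1. Reads counted to a neighbouring gene are argued against as the whole cause, since 8.8% of the low values were regained by a gene nearby. Genes prone to lost counts in any library may be the source: 56 genes were low in more than 1 library, where 1000 random draws gave at most 8. No biological explanation was tested.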
